A study of Bos taurus with 2 samples.

How the data were processed

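RNA was sequenced from seminiferous tubules of a calf aged 3 months and of a calf aged 9 months, with 1 library per age. Per the labels' protocols, pieces of tubule were cut from the removed testes and flash frozen, and libraries were made from total RNA extracted with a column kit. Per the submitters' processing notes, Trimmomatic 0.33 and STAR 2.4.0 were used with the bovine genome build UMD3.1. The counting program, the annotation release, the strand setting, the treatment of reads with several alignments and any molecular identifiers are not given in the sources used here.

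For each library the deposited table lists 24616 Ensembl genes. The deposited tables carry no header line, so the unit of each column was worked out from its values. A deposited column holds raw counts per gene, deposited as whole numbers with no normalization. Another deposited column holds the gene length in bases and is the same in both tables. The last deposited column is in RPKM, meaning counts per kilobase of that length and relative to the table's own total count, since it equals that quotient to the printed digits, with a largest difference of 0.000492% in the 3-month library and 0.000496% in the 9-month library. The RPKM column served only for this check. No columns of other samples were present, and the number left unused for that reason was 0.

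The raw counts were scaled to effective library sizes by the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3, which gave factors of 0.855 for the 3-month library and 1.17 for the 9-month library. Expression is given in CPM, the count of a gene relative to this effective size. A gene was measured when it had at least 10 counts over both libraries. Log2 ratios, always of the 9-month to the 3-month library, carry a prior count of 2. Folds between the libraries are ratios of scaled counts with a 95% exact interval (conditional binomial, Clopper-Pearson). Against 0 counts the fold is a bound, computed with a floor of 3 counts per library, which is 0.0933 CPM in the 3-month library and 0.0861 CPM in the 9-month library. Intervals and floors cover counting error only, and not differences between animals or pieces of tissue. They may be too narrow even for counting error, since PCR reads need not be independent molecules and any molecular identifiers are not given. Shares of a library's counts carry exact binomial intervals. Further computing used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

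With 1 library per age no test across genes is possible and no p-value is given. Genes were sorted by size alone, as at least 2-fold, 4-fold or 16-fold higher or lower. A member of a gene list was called higher or lower when it differed at least 2-fold with an interval that excluded a ratio of 1, and within 2-fold otherwise. The median log2 ratio of each list was set against 10000 random lists of the same size matched in 20 bins of mean expression, and its percentile among them is a description of these libraries. Percentiles are given only for lists with at least 4 measured members.

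Before the data were examined, 26 lists were fixed. They covered markers of undifferentiated spermatogonia and gonocytes, differentiating spermatogonia, meiotic prophase, late spermatocytes, round spermatids, elongating spermatids, Sertoli cells, immature Sertoli cells, mature Sertoli cells with the blood-testis barrier, Leydig cells with steroidogenesis, peritubular myoid and smooth muscle cells, endothelial cells, leukocytes with macrophages, red blood cells, and fibroblasts with extracellular matrix. The others were cell proliferation, the piRNA pathway, axoneme and flagellum, glycolytic enzymes of somatic cells, cholesterol synthesis and uptake, retinoid metabolism and signalling, imprinted and fetal growth genes, immediate early genes, cytosolic ribosomal proteins, mitochondrially encoded genes and reference genes. A further 9 lists, chosen after the data were seen, appear only among the closing observations.

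The rule for named genes was fixed at the same time. It took the 15 named genes with the highest and the 15 with the lowest log2 ratio among genes of at least 50 CPM in the higher library, leaving out histone, immunoglobulin, T cell receptor and ribosomal RNA genes. Of the genes ranked among the highest, 5 had no symbol or belonged to those families and were passed over, as were 7 among the lowest. It also took the 10 most abundant named genes of each library, up to 6 members of each list with the largest log2 ratios among members of at least 5 CPM (with the largest in each direction for lists that go both ways), and AMH, SOX9, STAR, CYP17A1, INSL3, GFRA1, UCHL1, KIT, STRA8, SYCP3, PIWIL1, PRM1, TNP1 and ACR whatever their values. From each list a few of these members are printed, and some genes that the rule takes are not reported here.

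Symbols are those of the tables. Of the 18025 measured genes, 15687 had a symbol. For the 339 symbols with more than 1 Ensembl gene, the gene with the most counts stood for the symbol in the gene lists. In the ranking by log2 ratio it was the gene with the more extreme ratio, and among the most abundant genes the most abundant one. In the comparison of chromosomes every measured Ensembl gene was counted, on the chromosome of its symbol. A list member absent under its current symbol was looked up under a synonym in a RefSeq gene table of assembly ARS-UCD2.0, so that IHO1 is listed as CCDC36, TERB2 as C10H15orf43, HSD3B1 as HSD3B and MSMO1 as SC4MOL. The same table gave each gene's chromosome for the comparison of X-linked with autosomal genes and matched 94.0% of the measured genes with a symbol, which are 81.8% of all measured genes. That assembly differs from the build of the counts, so no coordinates are printed. Among 4527 genes of at least 1000 counts in both libraries, 25 pairs made of 19 genes had equal length and counts equal to within 0.1 Poisson SD in both libraries. They included Ensembl genes of RPL39 and of RPL23A, 70-base genes of bta-mir-2904, and genes of 92 and 561 bases with no symbol. A 92-base gene had 94370 counts in the 3-month library and 2543 in the 9-month library. A bta-mir-2904-3 gene had 15351 and 1918, and a 561-base gene 4741 and 3748. Values of genes with near-identical copies, or that overlap another gene, are therefore uncertain.

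The calculation was tested on simulated counts for the comparison of the 3-month with the 9-month library, over 18024 genes. The simulated noise was counting error only. The altered genes came from those of at least 100 counts over both libraries and were raised and lowered in equal number. The test therefore does not show how the scaling behaves where many genes differ unevenly. Of 200 genes altered 4-fold, 100% were given the right direction. A direction was also given to 0.331% of the unaltered genes, and 95.7% of the intervals held the true ratio. Of 100 unaltered lists, 7 lay outside the central 95% of matched random lists. Alternatives covered the scaling (plain library totals, median-ratio size factors of DESeq2 1.42.0, upper-quartile scaling, and scaling to the list of reference genes), the count minimum, the prior count, thinning of the deeper library, leaving out the 100 most abundant genes before scaling, and the matching of random lists.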

Results

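Gene expression was measured by RNA sequencing in seminiferous tubules, the coiled tubes of the testis in which sperm cells develop, from a calf aged 3 months and a calf aged 9 months. Each age was represented by 1 library. The 3-month library held 37600534 counts and the 9-month library 29782234, over 24616 listed genes. At least 1 count was found for 19384 genes in the 3-month library and for 20582 in the 9-month library. The 10 most abundant genes took 11.26% of the counts in the 3-month library (95% exact binomial interval 11.25 to 11.27) and 7.85% in the 9-month library (7.84 to 7.86). Mitochondrially encoded genes took 8.68% (8.67 to 8.69) and 7.39% (7.38 to 7.40) of the counts. With them left out, the 10 most abundant genes took 7.91% and 3.30% of the remaining counts. With 1 library per age, no difference below has a replicate check, and each value compares these libraries, not the ages in general. Folds are given with their 95% exact counting interval in brackets.

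The comparison asked which genes differ in expression between tubules of the younger and the older calf. In the 9-month library, genes of meiosis, of spermatids and of the sperm tail were many times more abundant than in the 3-month library. Most listed genes of steroid and cholesterol synthesis, of the extracellular matrix and of the cytosolic ribosome were less abundant, as were 10 of 15 general Sertoli cell markers. The protamine gene PRM1 (ENSBTAG00000021493), which packs sperm DNA, stood at 0.404 CPM in the 3-month library and 1185 CPM in the 9-month library. The hormone gene AMH (ENSBTAG00000014955), made by immature Sertoli cells, stood at 1185 and 34.0 CPM. The 11 immature Sertoli markers together had 4 lower, 2 higher and 5 within 2-fold, with a median log2 ratio of -0.14. STAR (ENSBTAG00000033345), which carries cholesterol into mitochondria for steroid synthesis, stood at 6723 and 274 CPM.

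Of 18025 measured genes, 5104 were at least 2-fold higher in the 9-month library and 4126 at least 2-fold lower, while 8795 lay within 2-fold. The larger differences went mostly upwards, with 3044 genes at least 4-fold higher against 1423 lower, and 1289 genes at least 16-fold higher against 97 lower. In the 3-month library 383 genes with at least 10 counts in the 9-month library had 0 counts, and 17 genes showed the opposite. The balance depended on the scaling. Compared with TMM, the change of scaling factors shifted log2 ratios by 0.45 with plain library totals, 0.42 with scaling to reference genes and -0.10 with upper-quartile scaling. The share of higher genes among those at least 2-fold different was 55.3% with TMM, 70.9% with plain library totals, 69.9% with reference genes and 51.7% with upper-quartile scaling. Among those at least 4-fold different it was 68.1%, 81.4%, 80.8% and 64.0% in the same order.

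**Figure D1:**
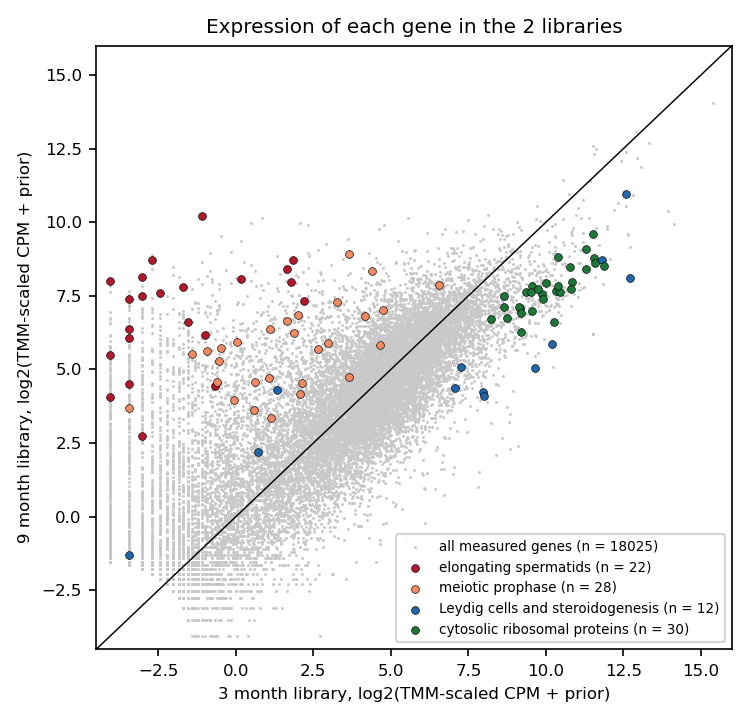
Each point is 1 of the 18025 measured genes, with its log2 CPM in the 3-month library on the horizontal axis and in the 9-month library on the vertical axis, and the line marks equal values. The 22 elongating spermatid genes and the 28 meiotic genes lie above the line, all 30 ribosomal protein genes lie below it, and the 12 Leydig cell genes lie on both sides.

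Genes of the male germ line from meiosis onwards were higher in the 9-month library almost without exception. All 28 measured genes of meiotic prophase were higher, with a median log2 ratio of 4.0. Among them SYCE3 and SYCE1, parts of the synaptonemal complex that holds paired chromosomes together, were 148-fold [80.1 to 308] and 62.9-fold [40.6 to 103] higher. HORMAD2, a protein of unpaired chromosome axes, was 105-fold higher [63.4 to 188], and MEIOB, which acts in meiotic recombination, 81.3-fold higher [53.0 to 132]. SYCP3, another synaptonemal complex gene, was already at 7.75 CPM in the 3-month library and reached 58.8 CPM in the 9-month library. All 14 measured markers of late spermatocytes were higher, with a median of 4.79. PIWIL1 (ENSBTAG00000006468), which binds the small piRNAs of germ cells, stood at 1.15 and 398 CPM, a 346-fold difference [251 to 492]. LDHC, the lactate dehydrogenase of germ cells, was 108-fold higher [88.6 to 134], and NME8 had 0 counts in the 3-month library and 1005 in the 9-month library, so that it was at least 309-fold higher.

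Spermatid genes showed the widest differences of the lists. Of 28 measured markers of round spermatids 27 were higher, with a median log2 ratio of 7.34, or 7.18 with the 4 members at 0 counts set at their bound. ACR, the protease acrosin of the acrosome, was 520-fold higher [203 to 1908], from 4 counts to 2252. ACTL7B, an actin-like protein of spermatids, went from 1 count to 6476, a ratio of 5976 [1072 to 236070]. The exception was CATSPER2, which was 2.19-fold lower [2.07 to 2.33]. Its annotated neighbour PDIA3, with which it overlaps in assembly ARS-UCD2.0, had almost the same log2 ratio (-1.13 for each), so the value of CATSPER2 is uncertain. All 22 measured markers of elongating spermatids were higher, with a median of 8.82, or 8.54 with the 3 members at 0 counts set at their bound. Their summed expression was 17.9 CPM in the 3-month library and 4775 CPM in the 9-month library. TNP1 and TNP2, the transition proteins that replace histones before the protamines, had 2 and 3 counts in the 3-month library and 9897 and 14549 in the 9-month library, which are ratios of 4566 [1264 to 37711] and 4475 [1531 to 21703]. ODF1 (ENSBTAG00000003445), a protein of the outer dense fibres of the tail, went from 0 counts to 8961 and was at least 2756-fold higher. With a prior count of 10 the medians of round and elongating spermatids were 5.78 and 7.51. In each of the germ cell lists from meiotic prophase onwards the median lay above all 10000 matched random lists.

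The piRNA pathway and the sperm tail followed the same direction. Of 18 piRNA pathway genes 16 were higher and 2 lay within 2-fold, with a median log2 ratio of 4.0. The RNA helicase gene DDX25 was 44.4-fold higher [39.3 to 50.2] and TDRD6, a scaffold of germ granules, 35.7-fold [30.8 to 41.5]. All 28 genes of the axoneme and flagellum were higher, with a median of 5.03. ROPN1L was 596-fold higher [348 to 1120], RSPH1, part of the radial spokes, 407-fold [233 to 789], and the tektin gene TEKT4 at least 327-fold, from 0 counts to 1063. Both medians lay above all matched random lists.

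Spermatogonial genes differed far less. Of 18 measured markers of undifferentiated spermatogonia and gonocytes 5 were higher, 2 lower and 11 within 2-fold, with a median log2 ratio of 0.68 at the 72.9th percentile of matched random lists. With plain library totals 10 of them were higher. GFRA1, the receptor of a niche growth factor, had only 47 and 80 counts and was 1.57-fold higher [1.08 to 2.30]. UCHL1 was 1.67-fold higher [1.54 to 1.82], SALL4 4.34-fold higher [3.36 to 5.66] and TSPAN33 4.91-fold lower [4.39 to 5.51]. Of 10 markers of differentiating spermatogonia 4 were higher, 2 lower and 4 within 2-fold, with a median of 0.16 at the 54.0th percentile. DMRTB1, which acts at the switch from mitosis to meiosis, was 76.4-fold higher [32.5 to 237]. STRA8, a retinoic acid target at the start of meiosis, was 1.75-fold higher [1.52 to 2.01], KIT 1.54-fold lower [1.45 to 1.63] and CCND2 2.99-fold lower [2.49 to 3.59]. Of 19 proliferation genes 11 were higher, 1 lower and 7 within 2-fold, with a median of 1.20 at the 99.95th percentile. BUB1 and PLK1, both kinases of mitosis, were 7.95-fold [7.24 to 8.75] and 6.15-fold [5.50 to 6.88] higher, and RRM2 was 2.11-fold lower [1.88 to 2.36].

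Sertoli cells, the somatic nurse cells of the tubule, were covered by 3 lists, of which the general markers were mostly lower in the 9-month library. Of 15 general Sertoli markers 10 were lower, 1 higher and 4 within 2-fold, with a median log2 ratio of -1.52 at the 0.27th percentile. INHA, which encodes the inhibin alpha chain, was 10.5-fold lower [10.3 to 10.8] and FSHR, the receptor of follicle-stimulating hormone, 6.38-fold lower [5.96 to 6.83]. CLDN11, a tight junction protein of the blood-testis barrier, went the other way, from 6.44 to 319 CPM, and was 49.6-fold higher [43.2 to 57.2]. SOX9 was 1.44-fold higher [1.22 to 1.70]. Among 11 markers of immature Sertoli cells 4 were lower, 2 higher and 5 within 2-fold, with a median of -0.14 at the 47.3rd percentile that turned to 0.31 with plain library totals. AMH was 34.8-fold lower [32.9 to 36.9] and INHBA 6.33-fold lower [5.84 to 6.87], while KRT8 was 6.37-fold higher [4.87 to 8.45]. Among 13 markers of mature Sertoli cells and the blood-testis barrier 6 were lower, 1 higher and 6 within 2-fold, with a median of -0.48 at the 25.1st percentile. GJA1, a gap junction protein, was 4.51-fold lower [4.33 to 4.71].

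Leydig cells lie between the tubules and make androgens. Their list had the lowest median of the 26, at -2.89 on the log2 scale, below all matched random lists, with 9 of 12 members lower and 3 higher. STAR was 24.6-fold lower [24.1 to 25.1], CYP11A1, the first enzyme of steroid synthesis, 24.1-fold [22.7 to 25.6], CYP17A1 8.54-fold [8.40 to 8.69] and INSL3 3.09-fold [3.07 to 3.12]. HSD17B3, which makes testosterone, was 8.13-fold higher [6.42 to 10.4]. Cholesterol synthesis and uptake was lower as well, with 16 of 18 genes lower, 2 within 2-fold and a median of -2.51, also below all matched random lists. DHCR7, an enzyme of the final steps of cholesterol synthesis, was 22.8-fold lower [20.8 to 24.95] and HMGCS1 14.9-fold [14.3 to 15.6].

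The other somatic lists had members on both sides, and the fibroblast, endothelial and leukocyte lists had more lower than higher members. Among 18 genes of fibroblasts and extracellular matrix 10 were lower, 1 higher and 7 within 2-fold, with a median log2 ratio of -1.43 at the 0.3rd percentile, or the 9.48th of lists matched on the 3-month library alone. LUM was 80.0-fold lower [68.0 to 94.7], SPARC 11.9-fold [11.7 to 12.0] and the basement membrane collagen COL4A1 10.2-fold [9.999 to 10.5], while the elastin gene ELN was 4.26-fold higher [4.07 to 4.46]. Among 10 endothelial markers 8 were lower, 1 higher and 1 within 2-fold, with a median of -1.24 at the 0.65th percentile, and 3 were lower with plain library totals. PECAM1 was 3.86-fold lower [3.37 to 4.44] and VWF 5.91-fold higher [5.27 to 6.64]. Among 15 markers of leukocytes and macrophages 7 were lower, 2 higher and 6 within 2-fold, with a median of -0.91 at the 1.87th percentile, or the 4.18th when matched on the 3-month library alone, and 3 were lower with plain library totals. C1QB was 4.93-fold lower [4.64 to 5.24] and AIF1 3.30-fold higher [2.99 to 3.65]. Among 9 markers of peritubular myoid and smooth muscle cells 2 were higher, 3 lower and 4 within 2-fold, with a median of 0.01 at the 59.7th percentile that turned to -0.09 with upper-quartile scaling. With plain library totals and with reference genes 0 were lower, and the medians were 0.46 and 0.43. MYH11 and ACTA2, proteins of the contractile apparatus, were 4.89-fold [4.64 to 5.16] and 2.88-fold [2.76 to 3.01] higher, and CNN1 was 2.30-fold lower [2.06 to 2.57]. Only 3 red blood cell genes were measured, all near the floor and named after their values were seen. HBB had 31 and 0 counts, HBA 20 and 7, and AHSP 24 and 41, and their median was -1.39. With a minimum of 50 counts only AHSP was left, and the value of 0.63 was its own ratio.

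**Figure D2:**
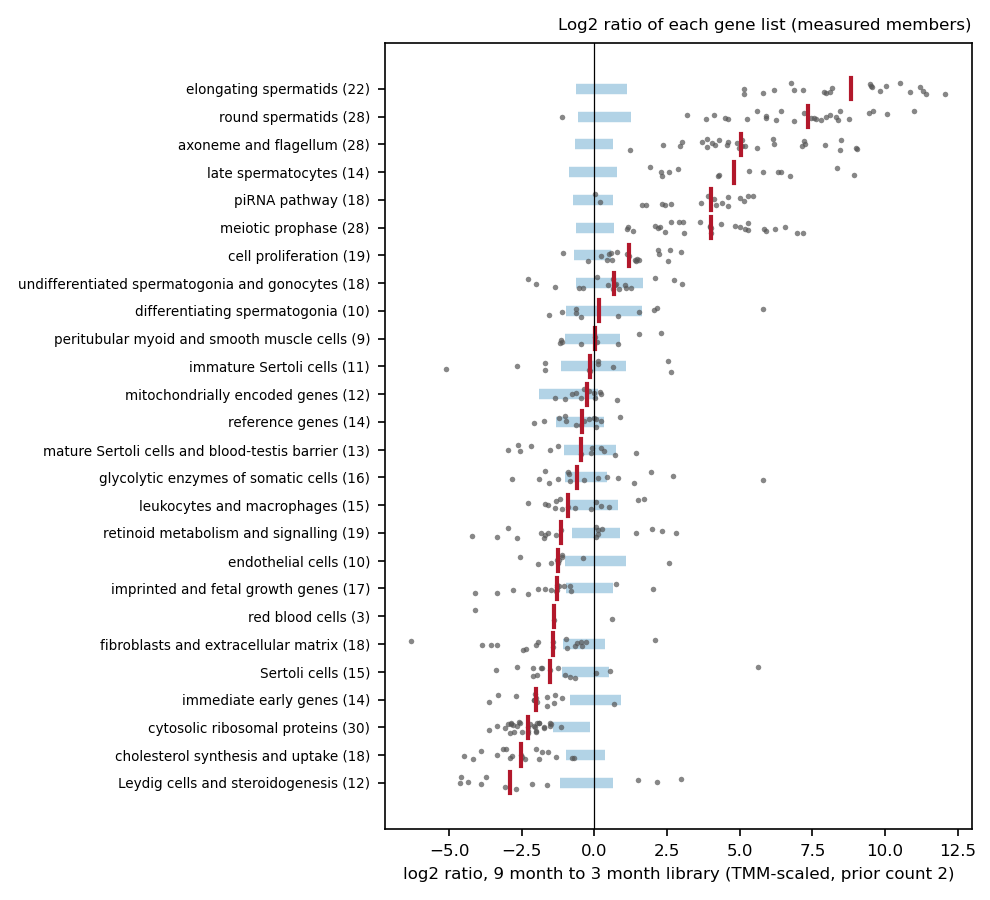
Each grey point is a measured member of 1 of the 26 gene lists, with its log2 ratio of the 9-month to the 3-month library on the horizontal axis and the number of measured members beside the list's name. Red bars are list medians, from -2.89 for Leydig cells to 8.82 for elongating spermatids, and blue bars span the central 95% of 10000 matched random lists.

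Metabolic and growth genes were fixed as further groups. Of 16 glycolytic genes of somatic cells 4 were higher, 5 lower and 7 within 2-fold, with a median log2 ratio of -0.60 at the 18.7th percentile. Within the group SLC2A3, a glucose transporter, went from 12.1 to 682 CPM and was 56.4-fold higher [51.0 to 62.5], and LDHA was 6.55-fold higher [6.09 to 7.05]. LDHB was 7.23-fold lower [6.98 to 7.50] and PGK1 3.77-fold lower [3.62 to 3.93]. Of 19 genes of retinoid metabolism and signalling 10 were lower, 4 higher and 5 within 2-fold, with a median of -1.16 at the 0.15th percentile, or -0.58 with no minimum beyond 1 count. The retinol carrier receptor STRA6 was 19.3-fold lower [14.6 to 26.1] and ALDH1A1, an enzyme that makes retinoic acid, 7.89-fold lower [7.75 to 8.03]. ALDH1A2, another such enzyme, was 5.01-fold higher [4.69 to 5.35], and CYP26B1, which breaks retinoic acid down, 7.04-fold higher [5.99 to 8.32]. Of 17 imprinted and fetal growth genes 13 were lower, 1 higher and 3 within 2-fold, with a median of -1.28 at the 0.44th percentile, and 7 were lower with plain library totals. CDKN1C, which restrains the cell cycle, was 17.4-fold lower [14.96 to 20.4] and GPC3 7.11-fold lower [6.02 to 8.45], whereas IGF2BP1 was 4.07-fold higher [3.34 to 4.99].

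Among the lists that reflect the state of a sample, the ribosomal protein and immediate early lists were lower in the 9-month library, and the mitochondrially encoded and reference lists stayed within the range of random lists matched on mean expression. All 30 cytosolic ribosomal protein genes were lower in the 9-month library, with a median log2 ratio of -2.29, and their summed expression was 40179 CPM in the 3-month library and 7428 CPM in the 9-month library. RPL37 was 12.5-fold lower [12.0 to 12.9] and RPL5 10.3-fold [10.1 to 10.5]. The median lay below all random lists matched on mean expression, but at the 34.35th percentile of lists matched on 3-month expression and gene length, a match chosen after the data were seen whose random lists also drew other ribosomal protein genes. With other ribosomal protein genes and all genes with no symbol left out of the random lists, the median lay at the 0.48th percentile. This was below their central 95% of -2.13 to -1.07, and the effect of each omission alone was not tested. Of 14 immediate early genes, which respond within minutes to handling or stress, 13 were lower and 1 was within 2-fold, with a median of -2.0 below all matched random lists. FOS was 12.6-fold lower [10.8 to 14.8] and MYC 10.01-fold [8.48 to 11.9]. Of 12 mitochondrially encoded genes found under the symbols of the fixed list 2 were lower and 10 within 2-fold, with a median of -0.28 at the 87.1st percentile, or the 99.82nd when matched on the 3-month library alone, that turned to 0.18 with plain library totals, under which none was lower. COII, a mitochondrially encoded gene that the list held under other names, was 2.32-fold lower [2.30 to 2.33], and with it 3 of 13 were lower, with a median of -0.35 at the 83.3rd percentile. COX1 was 2.55-fold lower [2.54 to 2.56] and ND5 1.70-fold higher [1.69 to 1.71]. Of 14 reference genes 4 were lower and 10 within 2-fold, with a median of -0.42 at the 54.0th percentile that turned to 0.03 with plain library totals, under which 2 were lower. B2M was 4.20-fold lower [4.13 to 4.26]. Of the 25 fixed lists with a percentile, 7 lay above and 10 below the central 95% of random lists matched on mean expression, and 8 above and 8 below that of lists matched on the 3-month library alone. If members varied independently, 1.25 would be expected outside it, while 7 of 100 unaltered simulated lists lay outside. Members of a list may vary together between animals or pieces of tissue, so neither figure is a chance rate for these lists.

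Ranked without regard to lists, among 5568 genes of at least 50 CPM in either library, the 15 highest log2 ratios included those of ODF1, C25H16orf82, TNP2, PRM1, TNP1, GK2, ACTL7B, CETN1, HMGB4, HSPB9, SPZ1, CABS1, SMCO2 and PDHA2. PRM1 had the most counts of them, 13 in the 3-month library and 41274 in the 9-month library, a ratio of 2930 [1713 to 5503]. SPZ1 and SMCO2 had 0 counts in the 3-month library and were at least 1033-fold and 1010-fold higher. The 15 lowest were PLA2G1B, CHGA, COL21A1, FBN3, LUM, CCL25, KLK1, PCOLCE2, CAPN6, TM7SF2, ANG, CHRD, AMH, SCG5 and ANG2. PLA2G1B, a secreted phospholipase, was 114-fold lower [89.5 to 146], CHGA, a protein of secretory granules, 106-fold [91.4 to 123], and the collagen gene COL21A1 93.0-fold [79.9 to 109]. The chemokine gene CCL25 was 64.5-fold lower [49.5 to 85.6] and TM7SF2, a sterol reductase, 45.5-fold [35.6 to 59.2]. ANG and ANG2 overlap each other and RNASE4 in assembly ARS-UCD2.0, so their separate folds of 41.6 [37.6 to 46.1] and 35.0 [28.8 to 42.9] are uncertain.

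The most abundant named genes also differed. In the 3-month library they were COX1, TIMP2, SPARC, ATP6, COII, ND1, COX3, EEF1A1, STAR and GSTA1. TIMP2, an inhibitor of matrix-degrading proteases, stood at 17876 CPM there and at 990 CPM in the 9-month library, 18.1-fold lower [17.9 to 18.3]. GSTA1, a glutathione transferase, was 11.7-fold lower [11.5 to 11.9] and the translation factor EEF1A1 3.67-fold lower [3.64 to 3.70]. In the 9-month library they included COX1, COX3, ATP6, UBB, MT-CYB, ND5, ND1, MT-ND4 and COII. UBB, which encodes ubiquitin, was 2.09-fold higher [2.08 to 2.11].

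X-linked genes were set against autosomal genes because germ cells silence the X chromosome during meiosis. The 498 measured X-linked genes had a median log2 ratio of -0.92 and the 14208 autosomal genes a median of 0.03. The difference was -0.95 (95% bootstrap interval over genes -1.14 to -0.77, in which genes are not independent replicates). The X median lay below those of all 10000 autosomal sets matched on mean expression, which spanned -0.12 to 0.18 over their central 95%. The medians of the 29 autosomes taken singly ran from -0.21 to 0.25. On the X chromosome 238 genes were lower and 70 higher, or 47.8% and 14.1%, against 21.3% lower and 26.9% higher on the autosomes. PGK1 and PDHA1, X-linked genes of energy metabolism, were 3.77-fold [3.62 to 3.93] and 3.25-fold [3.06 to 3.45] lower. AKAP4, an X-linked gene of the fibrous sheath of the sperm tail named after its value was seen, was an exception at 112-fold higher [91.7 to 138].

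**Figure D3:**
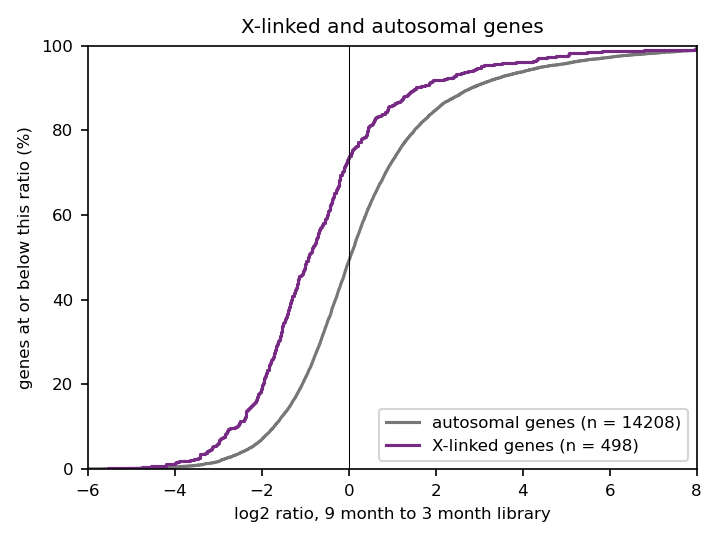
The curves give the percentage of X-linked genes (498, purple) and autosomal genes (14208, grey) at or below each log2 ratio of the 9-month to the 3-month library. The X-linked curve lies to the left, with medians of -0.92 and 0.03.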

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

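All alternatives below were planned before the data were examined, except the match of random lists on gene length, the summing of Ensembl genes that share a symbol, the counting of COII among the mitochondrially encoded genes, the recount under each scaling of the somatic markers together and of the lists chosen after seeing the data, and the omission of genes with no symbol, which were all chosen at that later stage. No paired analysis was possible because each age had 1 library. Of the counts, medians and percentiles that answer a comparison, 571 alternative values stayed within 1.5 times the main count, within the counting interval of the main median or on the same side of the percentiles. Of the others 24 counts or percentiles were weaker, 3 were stronger and 76 medians or shares moved. No list median beyond the percentiles changed sign, whereas those of immature Sertoli cells, myoid cells, mitochondrially encoded genes and reference genes did. The red blood cell value changed sign only with a minimum of 50 counts, which left AHSP alone in the list. With plain library totals, 2692 genes were at least 2-fold lower in place of 4126 and 859 at least 4-fold lower in place of 1423, and with scaling to reference genes 881 were at least 4-fold lower. Under either scaling, 10 markers of undifferentiated spermatogonia and gonocytes were higher in place of 5. Under either, the lower members numbered 0 of the peritubular myoid list in place of 3, 3 of the endothelial list in place of 8, 3 of the leukocyte list in place of 7, 1 of the red blood cell list in place of 2, 7 of the imprinted list in place of 13, 0 of the mitochondrially encoded list in place of 2, and 2 of the reference genes in place of 4. The median log2 ratios, first with plain library totals and then with scaling to reference genes, were 1.12 and 1.08 for undifferentiated and 0.61 and 0.58 for differentiating spermatogonia, 4.44 and 4.41 for meiotic prophase, 5.24 and 5.21 for late spermatocytes, 7.70 and 7.68 for round and 9.19 and 9.16 for elongating spermatids. In the same order they were -1.07 and -1.10 for Sertoli cells, 0.31 and 0.27 for immature and -0.029 and -0.062 for mature Sertoli cells, -2.44 and -2.48 for Leydig cells, 0.46 and 0.43 for myoid cells, -0.79 and -0.83 for endothelial cells, -0.46 and -0.49 for leukocytes, and -0.98 and -1.01 for fibroblasts. They were 1.65 and 1.62 for proliferation, 4.45 and 4.41 for the piRNA pathway, 5.47 and 5.44 for the axoneme, -0.15 and -0.18 for glycolysis, -2.06 and -2.10 for cholesterol, -0.83 and -0.86 for imprinted genes, -1.55 and -1.59 for immediate early genes, -1.83 and -1.87 for ribosomal proteins, 0.18 and 0.14 for mitochondrially encoded genes, and 0.033 and 0.000174 for reference genes. These shifts follow from the scaling itself, which adds nearly 1 constant to every log2 ratio. Upper-quartile scaling gave -3.00 for Leydig cells, -1.53 for fibroblasts, 1.10 for proliferation, -0.70 for glycolysis, -2.62 for cholesterol, -2.10 for immediate early genes, -2.39 for ribosomal proteins, -0.38 for mitochondrially encoded genes and -0.52 for reference genes. With no minimum beyond 1 count the median was -0.15 for mature Sertoli cells, -0.22 for red blood cells, -0.58 for the retinoid list, -2.30 for ribosomal proteins and -0.29 for mitochondrially encoded genes, and with a minimum of 50 counts it was -3.08 for Leydig cells, 0.63 for red blood cells and -0.26 for mitochondrially encoded genes. The last were at -0.26 with DESeq2 size factors and with the deeper library thinned. A prior count of 0.5 gave 7.73 for round and 9.91 for elongating spermatids, and a prior count of 10 gave 5.78 and 7.51, with 3.87 for meiotic prophase, since the prior sets the ratio of genes near 0 counts. Summing Ensembl genes gave -1.24 for Sertoli cells, and counting COII gave -0.35 for mitochondrially encoded genes. With DESeq2 size factors, and with a minimum of 50 counts, 1 mitochondrially encoded gene was lower. With that minimum AHSP alone stood for the red blood cell list and 0 were lower, and with a prior count of 10 there was 1. With random lists matched on the 3-month library, the percentile was 4.18 for leukocytes, 9.48 for fibroblasts and 99.82 for mitochondrially encoded genes, and with gene length matched as well it was 34.35 for ribosomal proteins. Without mitochondrially encoded genes the 10 most abundant genes took 7.91% and 3.30% of the counts of the 3-month and the 9-month library. The cause of the other differences was not tested. The difference between X-linked and autosomal medians was -0.93 among genes of at least 5 CPM in the 3-month library and -0.91 with a minimum of 50 counts. Depth limits genes with few counts, since 3 counts are 0.0933 CPM in the 3-month library.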

Other observations

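The 9 gene lists, the pairs of gene copies and the tests in this part were chosen after the data were seen, apart from the matched autosomal sets and the minimum of 5 CPM for X-linked genes, which were planned. Of 36 measured kinesins, which include motors of mitosis, 27 were higher in the 9-month library, 3 lower and 6 within 2-fold, with a median log2 ratio of 1.78 above all matched random lists. With plain library totals and with reference genes 28 were higher and 0 lower. KIF2B was 348-fold higher [160 to 951] and KIF17 190-fold [152 to 241], and KIF5C 46.2-fold [40.3 to 53.2]. Of 16 intraflagellar transport genes 9 were higher, 2 lower and 5 within 2-fold, with a median of 1.12 at the 99.9th percentile, from WDR19 at 2.75-fold lower [2.56 to 2.95] to IFT140 at 4.84-fold higher [4.50 to 5.22]. Under the same other scalings 12 were higher and 1 was lower. All 5 measured sperm genes of the ADAM family were higher, with a median of 7.38 at the 99.91st percentile. ADAM2, which acts in sperm binding, went from 6 counts to 12394 and was 1908-fold higher [875 to 5195].

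Glutathione transferases act in detoxification. Of 16 measured, 12 were lower under each scaling, with 3 within 2-fold and 1 higher, and their median log2 ratio was -2.72, below all matched random lists. GSTA2 was 12.4-fold lower [12.0 to 12.8] and GSTM1 7.50-fold [7.32 to 7.68], while GSTT3 was 124-fold higher [65.4 to 273]. Of 10 genes of MHC class II 8 were lower and 2 within 2-fold, with a median of -1.26 at the 1.17th percentile, and of 11 genes of MHC class I antigen presentation 6 were lower and 5 within 2-fold, with a median of -1.05 at the 8.13th percentile. These numbers depended on the scaling, since 3 genes of class II and 1 of class I were lower with plain library totals, and 4 and 1 with reference genes. Of 30 translation factors 16 were lower and 14 within 2-fold, with a median of -1.13 at the 4.16th percentile, and 10 were lower and 2 higher with plain library totals and with reference genes. TPT1 was 8.42-fold lower [8.32 to 8.53]. Of 58 mitochondrial ribosomal proteins 9 were lower, 1 higher and 48 within 2-fold, with a median of -0.29 at the 13.0th percentile, which was 0.16 with plain library totals and 0.12 with reference genes, where 9 and 8 were higher and 3 and 4 lower. With upper-quartile scaling 14 were lower. Nuclear-encoded subunits of the respiratory chain, 71 in number, had 18 lower, 1 higher and 52 within 2-fold, with a median of -0.49 at the 0.83rd percentile. With plain library totals 6 of these were lower and 6 higher, with a median of -0.039, and with reference genes 6 were lower and 5 higher, with a median of -0.072.

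Several X-linked genes have an autosomal copy used in male germ cells. Of 8 measured X-linked members of such pairs 5 were lower and 3 within 2-fold, with a median log2 ratio of -1.77. Of 6 measured autosomal copies 5 were higher and 1 was within 2-fold, with a median of 9.84. The copies GK2, CETN1 and PDHA2 were already among the 15 highest log2 ratios when the pairs were chosen. These counts and medians are therefore a description only. PDHA1 stood at 137 CPM in the 3-month library and 42.1 in the 9-month library, and its copy PDHA2 went from 1 count to 4995. CETN2 stood at 130 and 35.2 CPM, and CETN1 went from 2 counts to 7959. The ribosomal protein gene RPL10 stood at 797 and 155 CPM, and RPL10L at 0.280 and 61.7 CPM. CSTF2T, the copy within 2-fold, stood at 87.9 and 59.4 CPM.

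X-linked genes were lower than autosomal genes by 0.95 on the log2 scale. Their expression level does not account for this, since their median of -0.92 lay below the range of matched autosomal sets (-0.12 to 0.18). A few strongly higher autosomal testis genes do not account for it in these libraries either. The lower quartiles differed by -0.96 (bootstrap interval over genes -1.09 to -0.81, in which genes are not independent replicates). Genes silent at 3 months are also no sufficient account, because the difference was -0.93 (-1.07 to -0.74) among genes of at least 5 CPM in the 3-month library. Meiotic silencing of the X chromosome in the germ cells of the older calf stays open as an untested biological explanation, since whole tissue gives no values per cell type and the age was not replicated.

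The 30 ribosomal protein genes were lower, with a median of -2.29. Reads shared between Ensembl genes of the same symbol do not account for it. The 23 members whose symbol has a single Ensembl gene had a median of -2.21 (bootstrap interval over genes -2.59 to -2.02). Sharing with copies that carry another symbol or none could not be seen in this way and stays open. Small subunit size alone did not bring another set of genes as low. Ribosomal proteins were lower than respiratory chain subunits by a log2 difference of -1.79 (bootstrap interval over genes -2.22 to -1.42). Median lengths were similar, at 654.5 and 597 bases. The 71 respiratory chain genes were less abundant, however, with a summed 6744 CPM in the 3-month library against 40179 CPM for the 30 ribosomal protein genes. A part played by length therefore stays open. A loss of abundant transcripts, or of transcripts both short and abundant, stays open. Random lists of other named genes matched on length and 3-month expression had a median of -1.60 (-2.13 to -1.07), which is also low, and these matched genes had a median of only 324 CPM against 989 CPM. A lower ribosomal protein expression in germ cells than in the somatic cells of the younger calf may also be a cause and was not tested.

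The general Sertoli, Leydig, myoid, endothelial, leukocyte and fibroblast lists together held 79 measured somatic markers. The lists of immature Sertoli, mature Sertoli and red blood cells, with medians of -0.14, -0.48 and -1.39, were not included. Of the 79 somatic markers 47 were lower, or 31 with plain library totals and 33 with reference genes. Dilution by germ cell RNA was weighed as a cause. A single dilution factor stays open, as 35 of these markers lay outside 2-fold of their common median of -1.20 by more than counting error, 18 above and 17 below, but with 1 animal per age the usual spread between animals is unknown, and germ cells may express some markers. Fewer Leydig cells of the same make-up stay open for the same reason, with 7 of 12 members outside 2-fold of the list's median, or 4 of the 9 that were not higher. Less interstitial tissue in the 9-month piece stays open, because the Leydig and endothelial medians differed by -1.65 with an interval from -2.94 to 1.19. The age of the calf, a different cut of tissue and a change of expression within somatic cells remain open together.

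BEX2 has 2 Ensembl genes that went in opposite directions. ENSBTAG00000036028 stood at 93.8 CPM in the 3-month library and 21.6 in the 9-month library, and ENSBTAG00000032875 at 2.74 and 39.9 CPM.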
